A study of Homo sapiens with 2 samples.

How the data were processed

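Total RNA of HCT116 cells, an established human colorectal cancer line, was measured 96 h after transfection with an siRNA against the ETS transcription factor EHF (siEHF) or with a negative control siRNA (siControl), per the labels. Each condition has 1 array, so there were no replicates. No p-value was computed, and every difference below describes these 2 libraries and not the conditions in general. The arrays are 1-colour Agilent whole human genome expression arrays labelled with Cy3, and each holds 45015 spots, of which 43376 are not controls and carry 41000 different probes.

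Spot signals were extracted with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes, which also name limma without saying what it was used for. The deposited scanner tables give each spot's intensity on a linear scale. Per the file headers, the processed intensity is background-subtracted and spatially detrended within the array and is not normalised between arrays, so a brighter array stays brighter until it is scaled. The authors' value table holds log2 values. Set against the scanner tables in their row order, each column equalled the log2 processed signal minus that array's median over the 26004 spots well above background on both arrays, with a largest deviation of 0.0071 and a median of 0 in each column. Each column belongs to 1 array, and the table served as an alternative source of values. No other per-sample columns were present.

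The main values were log2 processed intensities minus the log2 of each array's 75th percentile over non-control spots. A probe was usable where it was well above background and neither saturated nor marked as an outlier on both arrays. Spots of a probe were averaged, and then the usable probes of a gene. Every difference is log2 siEHF minus log2 siControl. Genes at least 2-fold apart were counted by direction. A gene well above background on 1 array alone has only a bound, given as "at least N-fold". It sets the bright array's value against the higher of the lowest signal among probes well above background on the dim array and the dim probe's own signal. No fold is given where this ratio is under 1.

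The array's names are old, so probes were named through RefSeq accessions or, failing that, current or older symbols in a reference gene table. Of the 41000 probes, 23958 matched by accession, 2755 by symbol and 1032 by an older symbol, and 13255 kept the name of the array design. Each name kept from the array design was treated as a gene in the counts of genes and in the pool for random lists. Such names were left out of the comparisons of probes along a gene and of chromosomes. Probe positions are on hg18, the build in the file headers, and the exon or UTR under a probe was not annotated here.

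Genes named in the text follow a rule fixed before the data were examined. It takes EHF and, among others, RUVBL1, CDKN1A and MDM2, which are of interest from what is known of the study. It then takes the 10 highest and 10 lowest genes by log2 difference, the 3 largest bounds in each direction, and the 2 members with the largest difference in each gene list. For the 10 highest and 10 lowest, all usable probes had to point the same way and the brighter array's signal had to reach the median of its usable probes. Some genes that the rule takes are not reported here. Other list members are named as examples chosen after their values were seen. The 25 gene lists, fixed at the same time, cover p53 targets, ETS factors, RUVBL1-containing complexes, histone H2B ubiquitination, cell death, cell cycle, DNA repair, interferon, NF-kB, stress, epithelial, mesenchymal, Wnt, MAPK, cholesterol, hypoxia and intestinal genes, ribosomal and reference genes, and markers of fibroblasts, immune and endothelial cells. A probe was found for 532 of the 533 symbols. Each list's median was placed as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these libraries. The distance to the middle of those random lists is called the shift of the list.

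The procedure was tested on simulated data, in which 200 genes received known changes on a dimmer copy of the control array with the spot noise measured here. The copy kept the control array's calls of well above background, and the noise was small beside the known changes. The simulation therefore checks the calculation alone, and not the loss of dim genes or the spread between probes of a gene. In this simulation of siEHF against siControl over 24283 genes, 100% of 67 genes planted 3-fold apart and 100% of 66 planted 8-fold apart were counted as at least 2-fold apart, against 0% of 67 planted 1.5-fold apart and 0% of the 24083 left alone. Over the 18185 measured genes, 6.50% of 200 random lists of 25 genes fell outside the middle 95%, and a random list raised by 1.5 on the log2 scale reached percentile 100.

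Precision is limited by the number of arrays. Well above background were 34958 spots (80.6%) on the siControl array and 26627 spots (61.4%) on the siEHF array, and no spot was saturated. The negative control probes had a mean net signal of 32.1 on the siControl array and 72.3 on the siEHF array, and the latter lies outside the range allowed per the file headers, which bears on dim values of the siEHF array. Over 189 usable probes printed 10 times on each array, the median SD of the log2 difference was 0.07, which covers printing and scanning alone. Different probes of a gene differed more, with a median SD of 0.70 over 4579 genes. Each array lies on its own slide, so slide and condition cannot be told apart.

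The alternatives fixed before the data were examined were normexp background correction with an offset of 50, scaling by the median or by the 75th percentile over probes well above background on both arrays, quantile normalization, loess on mean signal, no filter on dim probes, brighter probes alone, outlier spots kept, the brightest probe of a gene, the authors' value table, thresholds of 1.5-fold and 3-fold, another background call, and list means. Scaling by spike-in controls and the use of the probe nearest the 3' end of each gene were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and normexp used limma 3.58.1 in R 4.3.3.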

Results

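HCT116 cells were profiled 96 h after transfection with an siRNA against EHF, an epithelial transcription factor of the ETS family, or with a negative control siRNA, on 1 array each. There were no replicates, and no difference below has a replicate check. The siControl array was the brighter one, with a 75th percentile of processed intensity of 1224 against 425.1 and 80.6% against 61.4% of spots well above background. Expression was measured on both arrays for 18185 genes, which include entries that kept a name of the array design. The comparison asks which transcripts differ when EHF is depleted, with RUVBL1, a chromatin-remodelling ATPase, and the p53 pathway of interest from what is known of the study.

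EHF itself was lower in the siEHF library. Its probe on chromosome 11 (hg18, 34638487 to 34638546) gave an intensity of 1172 in siControl and 43.5 in siEHF, a log2 difference of -3.23 after scaling, or 9.35-fold more in siControl, but -1.92 after normexp and -5.38 under spike-in scaling. RUVBL1 was also lower, by a log2 difference of -2.30 (4.93-fold more in siControl) at its probe on chromosome 3 (129302146 to 129302205). A second RUVBL1 probe was well above background on the siControl array alone. CDKN1A, the p53-induced cell cycle inhibitor p21, was higher in the siEHF library by 4.66 on the log2 scale (25.3-fold), with 4.37 and 4.95 at its probes on chromosome 6 (36762684 to 36762743 and 36760156 to 36760215). MDM2, the ubiquitin ligase that degrades p53, was higher by 2.11 (4.32-fold), with 1.75 and 2.47 at its probes on chromosome 12 (67489279 to 67489338 and 67520089 to 67520148), but its difference was -0.04 when the arrays were scaled by spike-in controls. Both MDM2 probes were dim, with unscaled intensities of 65.5 in siControl and 76.7 in siEHF at the former and 14.5 and 27.7 at the latter. Much of the MDM2 difference therefore depends on the scaling.

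The libraries differed widely. Of the 18185 genes, 4979 were at least 2-fold higher and 3512 at least 2-fold lower in the siEHF library, together 46.7%, and 1953 and 1229 were at least 4-fold higher and lower. The correlation of log2 signal between the arrays, across usable probes, was 0.829; probes are not independent replicates. Probes of one gene did not always agree, and among 1767 genes with several usable probes and a mean at least 2-fold apart, 164 had probes in opposite directions. All probes were at least 2-fold higher for 564 genes and at least 2-fold lower for 329. A further 6052 genes were well above background on the siControl array alone, 1251 of them with a bound of at least 2-fold, and 421 on the siEHF array alone, all with such a bound. These counts of bounds are not comparable, since the arrays' floors differed. The lowest scaled log2 signal of a probe well above background was -7.43 on the siControl array and -4.97 on the siEHF array. A gene seen on the siEHF array alone therefore passes a 2-fold bound almost by construction. The share of higher genes among those at least 2-fold apart was 58.6%, against 71.8% after normexp correction and 5.12% under spike-in scaling, which lowered every log2 difference by 2.15 and turned 6 of the 37 named genes that were higher in siEHF, MDM2 among them, to lower. It also turned the medians of 12 of the 13 gene lists with a median above 0, all but that of the fibroblast markers, to below 0, so lists are called higher or lower here relative to matched random lists, which a shift common to all genes does not move.

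**Figure D1:**
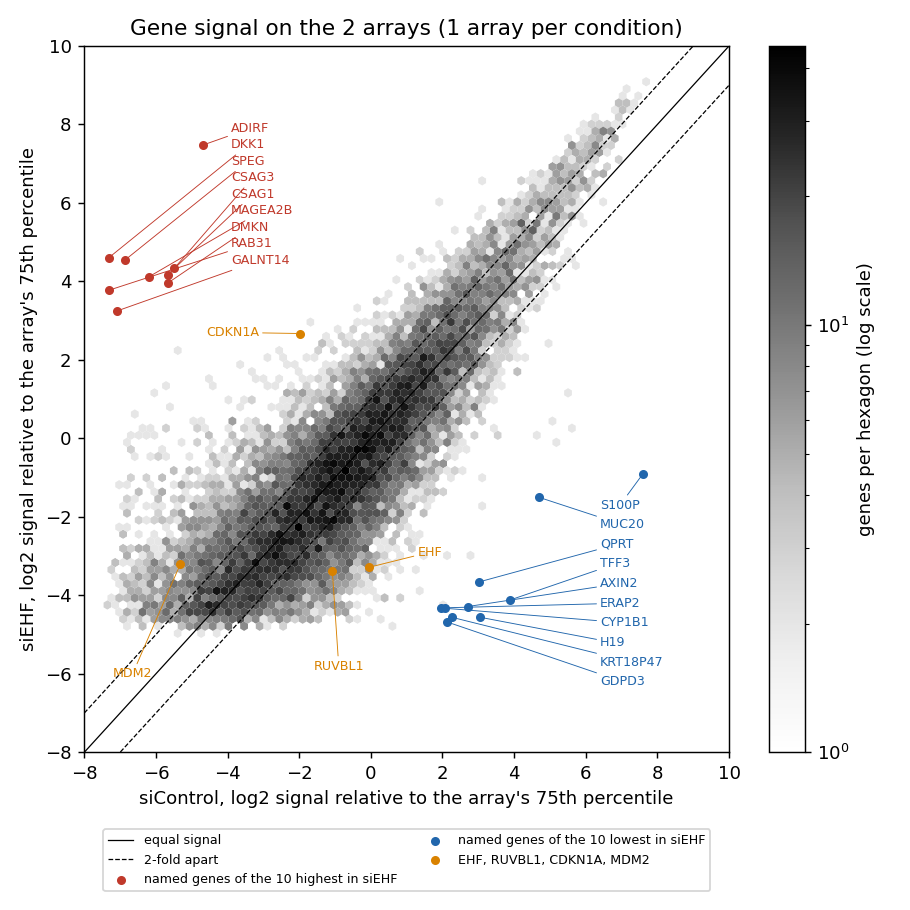
Log2 signal of 18185 genes on the siControl array (x axis) and the siEHF array (y axis), each relative to its array's 75th percentile, with 1 array per condition; grey hexagons are shaded by the number of genes on a log scale and dashed lines mark 2-fold differences. Genes named among the 10 highest in siEHF (red, ADIRF at 12.16) and the 10 lowest (blue, S100P at -8.50) lie far from the diagonal, and EHF (orange) lies below it at -3.23.

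Among genes measured on both arrays and bright on at least 1, the largest positive differences in the siEHF library belonged to ADIRF, an adipogenesis regulator (log2 difference 12.16), and DKK1, a secreted Wnt antagonist (11.91). SPEG, a muscle kinase (11.40), RAB31, a small GTPase of vesicle transport (11.09), and GALNT14, an O-glycosylation enzyme (10.34), came next. The 10 highest also included the epidermal secreted protein DMKN (9.63) and the cancer-testis genes MAGEA2B (10.31), CSAG1 (9.84) and CSAG3 (9.82), whose near-identical copies one probe may not separate. Among the same genes, the calcium-binding protein S100P had the largest negative difference (-8.50), with an intensity of 236363 in siControl and 226.9 in siEHF. After it came the trefoil peptide TFF3 (-7.995), the imprinted transcript H19 (-7.61), the Wnt feedback gene AXIN2 (-6.99), the pseudogene KRT18P47 (-6.84), whose probe may also bind keratin 18 transcripts, and GDPD3 (-6.80). QPRT, an enzyme of NAD synthesis (-6.67), the peptide-trimming protease ERAP2 (-6.38), the cytochrome CYP1B1 (-6.28) and the mucin MUC20 (-6.20) completed the 10 lowest. Several of these genes lay near the floor of the array where they were dim, which limits the size of their differences. DKK1 had a scaled log2 signal of -7.31 on the siControl array, where the lowest well above background was -7.43. H19 had -4.56 on the siEHF array, where the lowest was -4.97. On 1 array alone, the thioredoxin inhibitor TXNIP was at least 2744-fold lower in siEHF, the glutathione transferase GSTM3 at least 1854-fold and FAM50B at least 1052-fold. MSN, which links actin to the membrane, was at least 1257-fold higher and the kinesin KIF5C at least 1223-fold.

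The p53 target genes were higher as a group relative to genes of like signal, although spike-in scaling turned their median from 1.83 to -0.32, with 9 genes at least 2-fold higher and 12 lower. Of 33 measured under the main scaling, 22 were at least 2-fold higher and 3 at least 2-fold lower in siEHF, with a median of 1.83, a shift of 1.52 above matched random lists and percentile 100. They included the decoy death receptor TNFRSF10C (4.93), CDKN1A (4.66), the kinase PLK3 (3.98), the p53 phosphatase PPM1D (3.71) and the DNA repair gene DDB2 (3.34), while SESN2 (-2.09), CCNG1 (-1.16) and XPC (-1.10) were lower. EDA2R, another p53 target, was at least 81.1-fold higher, and 2 more targets were well above background on the siControl array alone. Over the 35 targets with a value or a bound the median was 1.83. The lists of cell death genes did not stand apart, and the pro-apoptotic one shares BAX, BBC3, PMAIP1 and APAF1 with the p53 list. Of 22 pro-apoptotic BCL2 family members and caspases, 6 were at least 2-fold higher and 3 lower (median 0.04, percentile 35.6), with HRK at 2.72 and CASP10 at -2.66. Of 12 anti-apoptotic genes, 2 were higher and 1 lower (median -0.24, percentile 16.3), with BIRC7 at 2.94 and BIRC6 at -2.68.

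Genes of cell division were lower in the siEHF library. None of 28 mitotic genes was at least 2-fold higher and 25 were at least 2-fold lower (median -1.98, shift -2.02, percentile 0), led by the topoisomerase TOP2A (-5.13), the kinesin KIF20A (-3.57) and the kinase AURKA (-3.34). AURKB and MKI67, a proliferation marker, were at least 16.5-fold and at least 5.79-fold lower. Of 27 DNA replication genes, 13 were at least 2-fold lower and 1, CCNE1 (1.24), higher (median -0.93, shift -1.10, percentile 0.01), with the flap endonuclease FEN1 at -3.69. DNA damage checkpoint and repair genes included 9 of 18 at least 2-fold lower and 3 higher (median -0.85, shift -0.98, percentile 0.46), with the checkpoint kinase CHEK1 at -2.82 and RPA2 at 2.08. Using the probe nearest the 3' end of each gene, which differs only for the 4 repair genes with several usable probes, the repair list lay at percentile 3.80.

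Among 21 measured ETS factors, 7 were at least 2-fold lower and 3 higher (median -0.71, shift -0.85, percentile 1.005). The 7 include EHF itself (-3.23), the siRNA target, which also enters the median and the percentile. ETS2 (-3.38), ETV4 (-2.88), SPDEF (-2.09) and ELF3 (-1.64) were lower as EHF was, and ETV1 (4.06), ELK3 (3.96) and ETS1 (1.46) were higher. Another ETV1 probe, well above background on the siControl array alone, was at -0.21, so the direction of ETV1 rests on 1 probe. The list left the lowest 2.5 percent after loess (percentile 5.35), after normexp (6.18), with the brightest (2.90) or 3'-most (3.98) probe of each gene, for its mean (4.04) and without the filter on dim probes (23.6). RUVBL1-containing TIP60 and INO80 complexes, which remodel chromatin, had 7 of 28 members at least 2-fold lower and 0 higher (median -0.20, percentile 12.8), with DMAP1 at -2.31 and -3.69 and -0.93 at its probes. Of 15 histone H2B ubiquitination genes, 4 were lower and 3 higher (median -0.39, percentile 12.3), and the ligase pair RNF40 (-2.86) and RNF20 (-2.34) had the largest differences.

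Relative to genes of like signal, epithelial genes were lower and mesenchymal genes higher as groups, although spike-in scaling turned the mesenchymal median from 1.60 to -0.56. Of 26 epithelial junction and keratin genes, 10 were at least 2-fold lower and 4 higher (median -0.72, shift -1.07, percentile 0.06), with the junction proteins CLDN4 at -2.49 and CDH1, E-cadherin, at -1.24, and with the adhesion genes JUP (1.62) and CDH3 (1.42) among those higher. Of 14 mesenchymal genes measured, 8 were at least 2-fold higher and 1 lower (median 1.60, shift 1.45, percentile 99.8), with fibronectin FN1 at 4.25 and the transcription factors TWIST1 at 3.42, SNAI1 at 3.24 and SNAI2 at 2.86. VIM, vimentin, was at -0.32, TGFBI was at least 858-fold lower, and ZEB1, ZEB2 and CDH2 were not well above background on either array. Intestinal differentiation genes included 5 of 10 at least 2-fold lower and 0 higher (median -0.61, percentile 11.3), led by TFF3 (-7.995) and TFF1 (-5.56). A further 10 were well above background on the siControl array alone, among them the intestinal transcription factor CDX2, at least 86.6-fold lower, and villin, VIL1, at least 30.4-fold lower, and with the 17 genes that had a value or a bound the median was -1.87. The list's mean lay at percentile 0.02. Of 14 Wnt targets, 6 were at least 2-fold lower and 1 higher (median -0.83, shift -0.88, percentile 1.35, but 9.10 for the list's mean), and with the brightest probe of each gene 3 were lower and 3 higher (percentile 7.02). AXIN2 stood at -6.99 and BMP4 at -4.56, ASCL2 was at least 637-fold and LEF1 at least 191-fold lower, and DKK1 stood at 11.91.

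Stress and signalling lists were mixed. Of 19 genes of endoplasmic reticulum stress and the amino acid response, 8 were at least 2-fold lower and 5 higher (median -0.69, shift -1.22, percentile 0.02). The lower ones included the amino acid response genes TRIB3 (-3.26, with -5.23 and -1.29 at its probes), PHGDH (-3.02) and ATF4 (-1.67), and the higher ones the chaperone HSPA5 (2.20) and SEL1L (2.20). Interferon-stimulated genes went both ways, with 9 of 20 at least 2-fold higher and 6 lower (percentile 50.05), as in IFI44 (3.06) and MX1 (-3.25). Their median was 0.12, but -0.64 with bounds for those on the siControl array alone. For NF-kB targets and chemokines, 6 of 14 were lower and 2 higher, with CXCL5 at -5.01 and LCN2 at -4.85, and the median of 0.44 (percentile 75.5) became -1.13 with bounds. MAPK feedback and immediate early genes included 6 of 20 higher and 2 lower (median 0.34, percentile 55.5), with DUSP4 at 4.46 and JUN at 3.996. Hypoxia and glycolysis genes included 9 of 23 higher and 1 lower (median 0.65, percentile 82.1), with the mitophagy receptor BNIP3 at 8.08, ADM at 3.42 and VEGFA at -1.92. Cholesterol synthesis genes (3 of 23 lower and 2 higher, median -0.13, percentile 18.04) held NSDHL at -3.77, and heat shock genes (2 of 12 lower and 2 higher, median 0.16, percentile 15.9) held HSPB1 at 1.77 and DNAJB1 at 1.73.

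**Figure D2:**
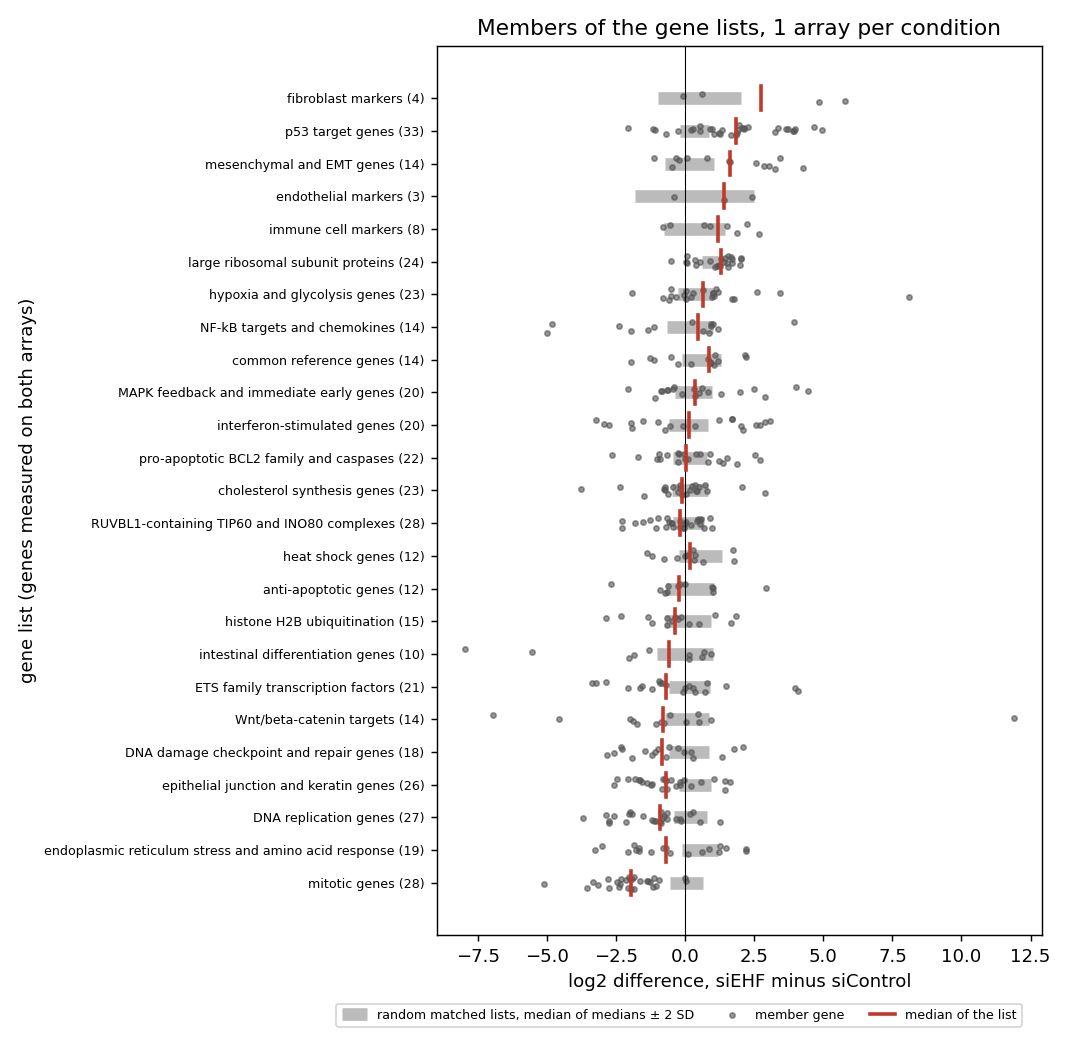
Log2 difference, siEHF minus siControl (x axis), of the members measured on both arrays (points) of 25 gene lists (y axis), 1 array per condition; red bars are list medians and grey bands the middle of random lists matched on mean signal ± 2 SD over 10000 lists. The medians of the mitotic genes (-1.98) and the p53 target genes (1.83, but -0.32 under spike-in scaling) lie outside their grey bands.

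Large ribosomal subunit genes, 16 of 24 at least 2-fold higher and 0 lower, had a median of 1.28, which lay at percentile 93.8 among lists as bright (99.5 with the 3'-most probe of each gene) and which spike-in scaling turned below 0. After loess 0 were higher and 1 lower (median 0.16, percentile 79.7), and after quantile normalization 1 was higher and 1 lower (median 0.25, percentile 83.6). RPL13 stood at 2.03 and RPL37 at 2.02, while another RPL37 probe, well above background on the siControl array alone, was at -2.08. Common reference genes had a median of 0.85 (5 of 14 higher, 3 lower, percentile 78.2), also turned below 0 by spike-in scaling, and ranged from SDHA at -1.97 to PPIA at 2.16 and TFRC at 2.19. Markers of other cell types were few. Of 4 fibroblast markers measured, COL1A1 (5.80) and COL5A1 (4.85) were higher and none lower (median 2.73, percentile 99.2, but 96.3 after normexp and 86.2 without the filter on dim probes). Of the others, COL1A2 and DCN were well above background on the siControl array alone, COL3A1 and LUM on neither, and with bounds the median was 0.30. Immune cell markers, a list that also holds globin genes, had 4 of 8 higher and 0 lower (median 1.19, percentile 92.8), with the globin HBA1 at 2.67. Endothelial markers had 2 of 3 higher and 0 lower (median 1.38, percentile 83.0), with CLDN5 at 2.43 and ESAM at 1.38. Another CLDN5 probe, well above background on the siControl array alone, was at -0.47. Probes along a gene differed between the arrays. In 4010 genes with probes apart on one strand, the probe nearer the 3' end was brighter by a median of 1.08 on the log2 scale on the siControl array and 1.63 on the siEHF array. The log2 difference was the higher one at the 3' probe in 71.7% of the genes with probes nearer than the median distance (3466 bases, introns included) and 61.9% of the others. The choice of that probe leaves most list members unaltered, since only 7 of 33 p53 targets and 7 of 26 epithelial genes had several usable probes.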

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

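The tests of spot noise, signal-dependent scaling and loss of RNA were chosen after the result was seen, and those of 5' ends, chromosomes and slide before. The spike-in controls stood out as a signal in probes that no gene comparison used. All 7 spike-in probes well above background on both arrays were brighter on the siEHF array before scaling, by a median of 0.63 on the log2 scale (1.55-fold, from 0.37 to 0.74), although the 75th percentile of the gene probes was 2.88-fold lower there.

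Of all measured genes, 46.7% lay at least 2-fold apart. Spot noise and signal-dependent scaling are argued against as the whole source, since the median SD over replicate spots was 0.0698 and 43.2% of genes were still that far apart after loess. A loss of 5' ends in the siEHF RNA may account for part, as the 3' probe had the higher log2 difference in 66.8% of 4010 genes, yet in 61.9% of those with probes farther apart and 71.7% of those nearer, with introns counted (a split not planned), where such a loss would be expected to show more with distance, and loss of RNA cannot raise a signal, and 4.09% of genes were at least 2-fold higher even under spike-in scaling, if spike-ins were added in equal amounts. The median differences of the 22 autosomes had an SD of 0.14, above all 1000 shuffles of genes over chromosomes (highest 0.13) and above 99.1% of shuffles once trends with signal and gene length were removed, so RNA from cells with another chromosome complement in one library remains a candidate explanation, although neighbouring genes regulated together would also spread these medians. Slide and scan day cannot be told apart from the siRNA with 1 array per slide and group, and a wide response to EHF depletion stays open and untested.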

How the results depend on the processing

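Spike-in scaling and the 3'-most probe were added after seeing the data. No paired analysis was possible because each condition has 1 array, and no array could be left out. No list outside the middle 95% of matched lists and no named gene turned direction relative to those lists or to all genes under the alternatives run on them, and causes were not tested. EHF stood at -3.23, and at -1.92 after normexp, -3.05 with median scaling, -3.42 with the percentile over detected probes, -3.13 after quantile normalization, -2.91 after loess, -3.15 in the authors' value table and -5.38 under spike-in scaling; it had no value among bright probes alone. Against 4979 genes higher and 3512 lower, the counts were 10625 and 6115 without the filter on dim probes and 2763 and 1536 with bright probes alone, where more or fewer genes were measured, 744 and 13791 under spike-in scaling, 2921 and 1929 at 3-fold, and 2147 lower after normexp. The median difference of all genes was 0.18, and 0.42 after normexp, 0.35 with median scaling, -0.01 with the percentile over detected probes and -1.97 under spike-in scaling. Among lists outside that middle 95%, shifts moved by more than the SD of random lists for p53 targets (1.25 after normexp, 1.25 after loess, 1.16 with bright probes), ETS factors (-0.40 after normexp, -0.28 without the filter), mitotic genes (-1.65 after normexp), mesenchymal genes (1.01 after normexp, 0.80 without the filter), fibroblast markers (0.88 and 0.60 likewise), endoplasmic reticulum stress genes (-0.81 after quantile normalization, -0.74 after loess) and repair genes (-1.42 with the brightest probe). Leaving out the 3 alternatives that shift all genes alike, 194 of 222 list values stayed within that SD and 28 did not, 15 of them in other lists, such as NF-kB targets (0.28, and -0.73 for the mean), intestinal genes (-0.59 and -1.68 likewise) and MAPK genes (0.05, and -0.39 after quantile normalization). Percentiles ranged from 0.84 to 23.6 for ETS factors, 0.05 to 9.10 for Wnt targets, 0.03 to 3.80 for repair genes, and 86.2 to 99.4 for fibroblast markers. Of 515 named gene values likewise, 426 moved by more than the spot SD. The dim siEHF array limits genes near its background.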

Other observations

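The gene families below, and the tests named here other than that of chromosomes and that of slide and scan day, were chosen after their values were seen. The percentiles of these families therefore only describe a choice made on the same values and lend no support. Of 7 HOXA genes, which set position along the body axis, 5 were at least 2-fold lower in the siEHF library and 0 higher (median -2.45, shift -2.58, percentile 0.01), as in HOXA13 (-4.41) and HOXA10 (-3.42), while HOXA9 stood at 0.12. Of 8 HOXB genes, 6 were at least 2-fold lower and 0 higher (median -2.23, percentile 0), as in HOXB6 (-4.74) and HOXB3 (-4.45). Clustered histone genes, which are expressed in S phase, included 25 of 53 at least 2-fold lower and 2 higher (median -0.92, percentile 0). Zinc finger genes of the ZNF series had a median of -0.46 over 284 genes, with 101 lower and 40 higher (percentile 0). Proteasome subunits included 7 of 36 lower and 1 higher (median -0.24, shift -0.67, percentile 0.34), with the immunoproteasome subunit PSMB9 at -2.75.

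All 10 measured metallothioneins, small metal-binding proteins, were at least 2-fold higher in the siEHF library (median 3.08, shift 2.27, percentile 100), from MT1E (1.19) to MT1L (3.71), though probes for such similar copies share transcripts. The 5 MAGE genes taken here, all of the MAGEA and MAGEB series and normally expressed in the testis, were higher as well (median 7.47), as in MAGEB2 (8.35) and MAGEA12 (7.47). One probe may not separate near-identical copies among them, and other MAGE series were not part of this family. Collagen chains included 12 of 21 higher and 5 lower (median 1.51, shift 1.33, percentile 99.95), as in COL6A2 (7.13), COL6A1 (6.65) and COL18A1 (4.96), against COL4A2 (-4.64) and COL16A1 (-4.22). Of 19 dual specificity phosphatases, some of which switch off MAP kinases, 11 were higher and 0 lower (median 1.06, shift 0.83, percentile 98.7), as in DUSP26 (5.28) and DUSP1 (3.64). All 14 pseudogenes of KRT18 were at least 2-fold lower (median -4.54). Their probes may also bind transcripts of KRT18 itself, so the 14 values may not be separate differences. KRT18 stood at -1.81 over 4 probes that did not all point one way. Spike-in scaling, which lowers every log2 difference by 2.15, turned the collagen and phosphatase medians below 0.

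The p53 target genes were higher relative to matched lists (percentile 100), although spike-in scaling turned their median from 1.83 to -0.32. Loess on mean signal took the list's shift from 1.52 to 1.25, against an SD of 0.25 for random lists. Those lists were already matched on mean signal, so loess could hardly remove the shift and does not decide on signal-dependent scaling. What the shift shows is a difference from genes of like mean signal. Loss of 5' ends stays open for the list, since only 7 of its 33 genes had several usable probes. A response of these genes to EHF depletion may underlie the pattern, as may a difference between the cells of the libraries, and neither was tested on this list. Slide and scan day cannot be told apart from the siRNA here, with 1 array per slide and group.

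Epithelial genes were lower and mesenchymal genes higher relative to matched lists, although spike-in scaling turned the mesenchymal median from 1.60 to -0.56. Loss of 5' ends stays open for the epithelial list, since only 7 of its 26 genes had several usable probes. Fibroblast RNA in the siEHF library stays open, since 4 of 12 fibroblast markers were well above background on that array and 10 on the siControl array, with COL1A1 (5.80) and COL5A1 (4.85) higher as were COL6A1 (6.65) and COL6A2 (7.13) but not COL6A3 (-0.09), while COL1A2, COL3A1, DCN and LUM, which fibroblasts make in abundance, were not well above background there. The loss of EHF, a factor of epithelial cells, is a possible explanation that stays untested, and so does RNA from other cells in one library, for which the spread of autosome medians (SD 0.14) leaves room, and slide and scan day cannot be told apart from the siRNA with 1 array per slide and group.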
